A study of Mus musculus with 29 samples.

How the data were processed

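Expression was measured in 29 mice, 1 array each, in 6 groups by genotype (HdhQ150 or wild-type littermate) and age (6, 12 or 18 months), on the mixed strain background that the labels name 129/Ola x C57BL6/J. Groups, ages, sexes and mouse numbers came from the labels. Total RNA of the caudate nucleus was extracted with TRIzol and chloroform and labelled with biotin by an Affymetrix WT labeling kit, per the labels' protocols. The deposited values are log2 expression levels made by the authors with Affymetrix Expression Console and RMA, per the submitters' processing notes, and no version is given there. RMA in general corrects background, normalizes quantiles and summarises probes by median polish, and its options are not given in the sources used here. Values ran from 1.08 to 14.11 with array medians of 6.91 to 7.05, and pairs of arrays correlated between 0.918 and 0.992. No pair of arrays held identical values. Every column of the table was used.

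The table held 35556 probe sets. The platform annotation named 23410 of them, 21789 with 1 gene symbol and 1621 with several, and 12146 are unnamed here. Of those with 1 symbol, 21698 matched a gene by Entrez ID in the RefSeq gene table of assembly GRCm38.p6, which was used for names alone, and 91 kept the annotation's name. Only probe sets with 1 symbol were tested. Where a gene had several (999 genes), the probe set with the highest mean over all arrays was kept, which left 19938 genes. Among called genes with several probe sets, 0 of 8 at 12 months and 0 of 1 at 18 months had another probe set past the threshold in the opposite direction. Unnamed probe sets and those with several symbols were counted in a second fit of all 35556 probe sets, with p adjusted over all of them.

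Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit, contrasts, eBayes with trend) on all 29 arrays with a mean for each of the 6 groups and a term for the labelled sex, so that every comparison shared 1 estimate of the spread with 22 residual degrees of freedom (prior degrees of freedom 6.91 at the median). P-values are two-sided and were adjusted by the method of Benjamini and Hochberg over all 19938 genes at a threshold of 0.05, with no fold threshold and no filter on dim probe sets. Differences are HdhQ150 minus wild type, or older minus younger. Genotypes were compared at each age, the differences were compared between ages, and ages were compared within wild type. Each replicate is a separate animal by its number in the labels.

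Of 32 gene lists, 29 were tested with limma's camera (two-sided, preset correlation between genes of 0.01), adjusted over the 29 lists. They covered markers of striatal projection, direct pathway and indirect pathway neurons, striatal interneurons, cortical and thalamic neurons, choroid plexus, ependyma, astrocytes, oligodendrocytes and their precursors, microglia and vessels. They also covered immediate early, cholesterol synthesis, heat shock, proteasome, respiratory chain, interferon, complement and antigen presentation, protocadherin, potassium channel, glutamate receptor, GABA receptor, presynaptic, calcium, homeobox, clock and glucocorticoid response genes. Blood markers had 1 measured gene, the genes beside Htt were described by counts, and sex chromosome genes served to check labels. A member of a list counts as adjusted over the list alone where its p passes after adjustment within that list. Camera with an estimated correlation and fry were run beside it (statmod 1.5.0 is used by limma). The list of newly formed oligodendrocyte genes was written after the genes changed were known and leaves those out.

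The text names, per comparison of genotypes, the 10 genes with the smallest p in each direction among those past the threshold, Htt and 10 genes fixed in advance (Drd1, Drd2, Penk, Pdyn, Tac1, Ppp1r1b, Adora2a, Cnr1, Pde10a and Gfap, of which Adora2a had no tested probe set), and up to 4 members of each list described. Comparisons of ages name 5 genes in each direction. Predicted genes and clones without a proper name were skipped but counted. Groups, tests, lists, this rule and the first set of alternatives were set before the data were examined.

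The scripts were tested on simulated data with 200 changed genes at log2 sizes of 0.3, 0.5 and 1 among 19938. At these sizes 38.8%, 85.1% and 100% were recovered for genotype at 6 months, 26.9%, 74.6% and 98.5% at 12 months and 25.4%, 77.6% and 97% at 18 months. For the change of the difference, recovery at size 0.5 was 52.2% between 6 and 12 months, 46.3% between 12 and 18 and 43.3% between 6 and 18. For wild type by age it was 76.1%, 74.6% and 70.1% at size 0.5. The simulated noise was independent between genes and arrays, with no outlying array, so recovery in the real data may be lower. The number of arrays limits the precision.

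Alternatives set in advance were all probe sets, no sex term, females alone, only the groups compared, the brighter part of the genes (the upper 50%), array weights, robust eBayes, no trend, a second quantile normalization, median centring and leaving out each mouse in turn. Females were taken by their label, so mouse 1023 is among them. Added after seeing the data were leaving out mouse WT-454 or 1023 in comparisons that do not use them, leaving out both, entering mouse 1023 as male, the mean of the cortical markers as a covariate, and camera on differences between ages. No array was left out of the reported fits. For counts of calls between genotypes or ages, other splits of the same mice, at most 100, were fitted in the same way. For changes of the genotype difference between ages, the residuals of a fit without that change were shuffled among the mice of each genotype instead. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.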

Results

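The study followed gene expression with age in a knock-in model of Huntington's disease. HdhQ150 mice carry an expanded CAG repeat inserted into the mouse huntingtin gene, Htt, and their wild-type littermates served as controls. RNA from the caudate nucleus, a part of the striatum, where neurons are lost in the disease, was hybridised to 29 arrays, 1 per mouse, at 6, 12 and 18 months of age. HdhQ150 groups held 5, 6 and 4 mice at the successive ages, and wild-type groups held 5, 5 and 4. Mice of different ages were different animals. The labels give 23 females and 6 males, and both 18-month groups held females alone. Array medians lay between 6.91 and 7.05 on the log2 scale, and the number of arrays limits the precision. Wild-type mouse WT-454 at 12 months stood apart, with a mean correlation of 0.945 with the other arrays of its group, against 0.975 to 0.978 for the other wild-type mice of that age. HdhQ150 mouse 1023 at 6 months, labelled female, had Xist at 5.95, inside the range of labelled males (5.50 to 6.13) and below that of the other labelled females (11.11 to 11.64). Its Y-linked Eif2s3y stood at 8.30, so the library labelled female did not match its label.

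Htt itself was lower in HdhQ150 mice at 6 and 12 months. At 6 months its level was 8.78 ± 0.06 (SD, n = 5) in HdhQ150 mice and 9.14 ± 0.03 (n = 5) in wild type, a log2 difference of -0.39 (SE 0.0619, limma adjusted p = 0.00457). In labelled females alone, mouse 1023 among them, the 6-month difference was -0.36 and missed the threshold (limma adjusted p = 0.125). Over all alternatives it ran from -0.415 to -0.364. At 12 months the levels were 8.65 ± 0.11 (n = 6) and 9.08 ± 0.13 (n = 5), a difference of -0.42 (SE 0.0589, limma adjusted p = 0.000122). The 18-month difference was -0.32 (SE 0.0684), from 8.85 ± 0.16 (n = 4) against 9.16 ± 0.04 (n = 4), and missed the threshold (limma adjusted p = 0.0523). Every HdhQ150 mouse lay below every wild-type mouse of its age, which chance gives in 0.397%, 0.216% and 1.43% of groupings at 6, 12 and 18 months. Mouse 1023 had the highest Htt of the 6-month HdhQ150 mice, at 8.88, and was still below the lowest wild-type mouse, at 9.11. The change of the Htt difference between ages did not pass for any pair of ages. Of 41 measured genes beside Htt, 0 passed at any age (limma). Their unadjusted p was under 0.05 for 7, 8 and 1 genes at 6, 12 and 18 months, and camera and fry were not run on this positional list.

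**Figure D1:**
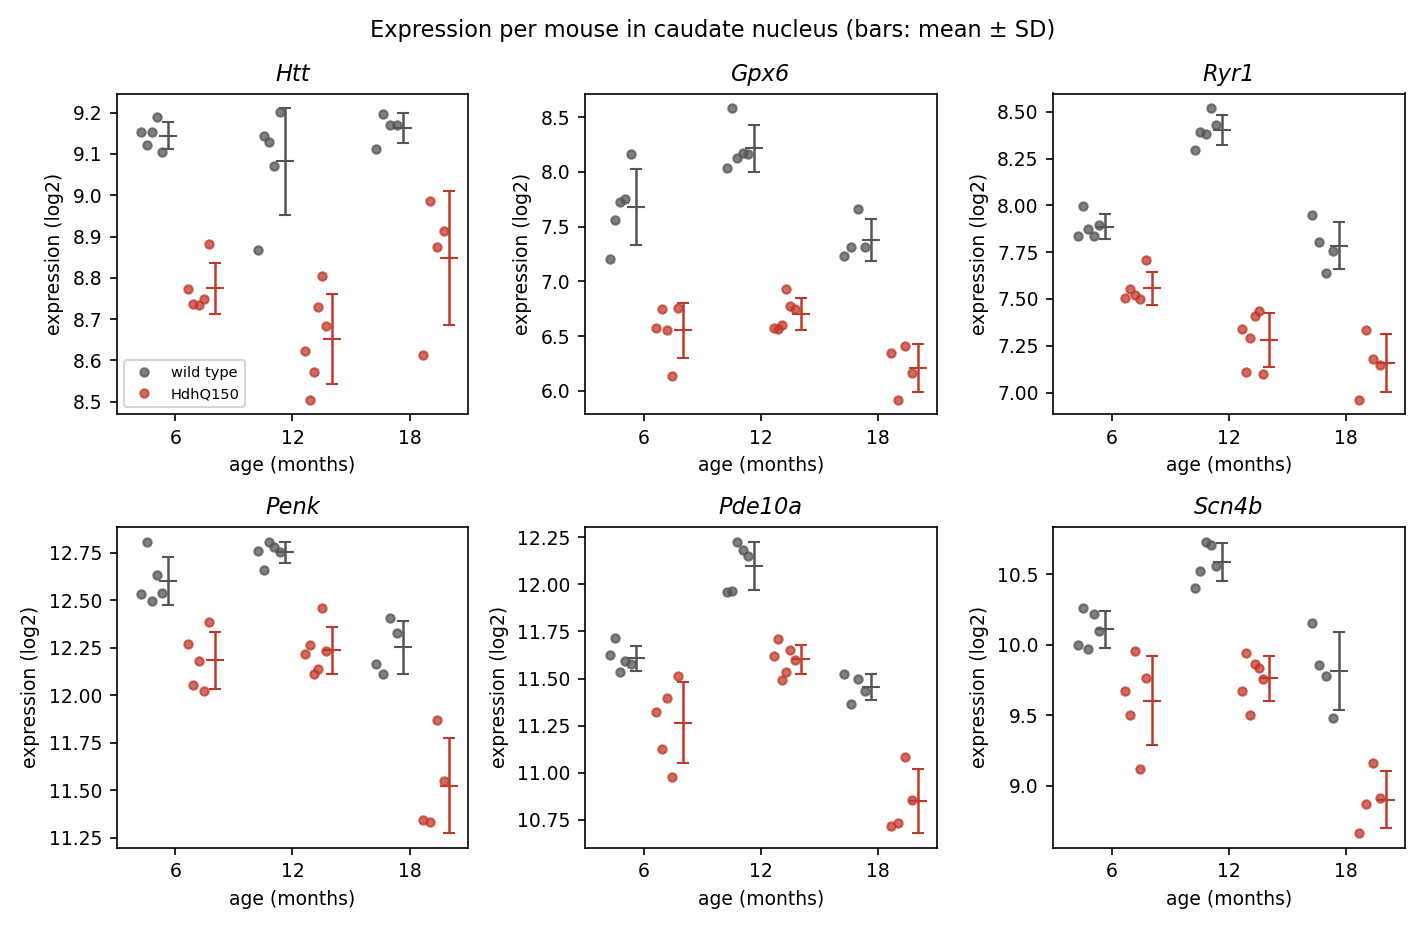
Expression (log2) of Htt, Gpx6, Ryr1, Penk, Pde10a and Scn4b in each mouse by age in months, wild type in grey and HdhQ150 in red, with the mean ± SD of each group as bars. Gpx6, Ryr1 and Scn4b were drawn because they were among the strongest calls, so the gap between genotypes in their panels (Ryr1 7.10 to 7.44 against 8.30 to 8.52 at 12 months) is no separate test.

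At 6 months 5 genes passed with all arrays weighted equally. The glutathione peroxidase gene Gpx6 (probe set 10403911) fell by 1.17 on the log2 scale in HdhQ150 mice, 2.25-fold, from 7.68 ± 0.35 to 6.55 ± 0.25 (SD, n = 5 each; limma adjusted p = 1.9e-05). Kcng1, which encodes a modifying subunit of voltage-gated potassium channels, rose by 0.53 (SE 0.0739, limma adjusted p = 0.000618). The endopeptidase gene Phex fell by 0.64 (SE 0.116, limma adjusted p = 0.0325). Insig1, a regulator of cholesterol synthesis, fell by 0.54 (SE 0.101, limma adjusted p = 0.0386). With Htt these made up the 5 genes past the threshold, 1 higher and 4 lower, of 19938 tested. By limma 2738 genes had an unadjusted p under 0.05 at this age, against 1790 at 12 and 1159 at 18 months. When nothing differs, a share of 0.05 of the 19938 genes is expected there, and the 1159 lie nearest to it. Genes are not independent, so these counts do not rank the ages. The count past the threshold was 1330 with array weights and 868 without mice WT-454 and 1023, and both included these 5. Genes typical of striatal projection neurons did not pass, among them Penk at -0.42 (limma adjusted p = 0.111), Pde10a at -0.34 (0.119) and Scn4b at -0.51 (0.119). Every HdhQ150 mouse still lay below every wild-type mouse for Penk (12.02 to 12.39 against 12.49 to 12.81). The same held for Pde10a (10.98 to 11.51 against 11.54 to 11.71). Chance gives this in 0.397% of groupings for 1 gene, and the genes that follow were not compared in this way. The dopamine receptor genes Drd1 and Drd2 stood at -0.25 and -0.21, Cnr1 at -0.21, Ppp1r1b at -0.17, Tac1 at -0.06, Pdyn at 0.09 and the astrocyte gene Gfap at -0.13, with limma adjusted p from 0.243 to 0.892. The count past the threshold depended on single mice. It was 188 without mouse 1023, 18 without wild-type mouse WT-454, 13 without WT-1011, 8 without 1003, and 3 without 1001, 1016, 1017, WT-1002, WT-1004 or WT-1020. Phex did not pass without 1001, 1016, 1017, WT-1002, WT-1004 or WT-1020 (adjusted p = 0.0522 to 0.186, range without any mouse in turn 0.00305 to 0.186), nor did Insig1 without these or WT-1018 (0.0836 to 0.2). With mouse 1023 entered as male, Phex and Insig1 missed the threshold too (-0.59 and -0.53, adjusted p = 0.0749 for both), as they did with no sex term, in females alone and with median centring.

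Gene lists fixed in advance shifted at 6 months even where their members did not pass singly, in the test with a preset correlation between genes. Markers of striatal projection neurons lay lower, with a median of -0.14 and 22 of 29 members negative (camera adjusted p = 0.000301, adjusted p = 0.849 with an estimated correlation). None of the 29 passed over all genes by limma, and 1 higher and 10 lower passed adjusted over the list alone. Markers of indirect pathway neurons, which express enkephalin and the D2 dopamine receptor, had a median of -0.21 (camera adjusted p = 0.000829, adjusted p = 0.494 with an estimated correlation). Of these 9, 0 passed over all genes, and 1 higher and 6 lower passed adjusted over the list alone, with Penk, Gpr6 at -0.42 and Gpr52 at -0.53 as examples. Cholesterol synthesis genes had a median of -0.076 (camera adjusted p = 0.000829, adjusted p = 0.68 with an estimated correlation). Insig1 fell, the other 18 of 19 did not pass, and 5 were lower adjusted over the list alone, with Cyp51 at -0.30, Msmo1 at -0.43 and Idi1 at -0.40. Calcium signalling genes (median -0.074), proteasome subunit genes (-0.14) and choroid plexus markers (-0.25) also shifted down, and microglia markers (0.12) and presynaptic vesicle genes (0.093) shifted up, with camera adjusted p from 0.0179 to 0.046. With an estimated correlation none of these 8 lists held (adjusted p = 0.494 to 0.896), and fry called none (adjusted p = 0.0571 to 0.593). Striatal interneuron markers (median 0.056, camera adjusted p = 0.133) and direct pathway neuron markers (-0.041, 0.471) did not shift. Respiratory chain genes had a median above 0 and a mean and camera direction below it (camera adjusted p = 0.846). The number of shifted lists was 13 without wild-type mouse WT-1018 and 5 without WT-1020. Single mice ended several calls: choroid plexus markers without 1003, WT-1002 or WT-1020 (medians -0.15, -0.11 and -0.098, adjusted p = 0.226 to 0.479), microglia markers without 1003 or WT-1011 (0.143 and 0.187), presynaptic genes without 1003, 1016 or WT-1020 (medians 0.031, 0.064 and 0.022, adjusted p = 0.146 to 0.232), proteasome genes without 1017 or WT-1020 (0.108 and 0.0889) or with mouse 1023 entered as male and calcium genes without 1017, WT-1004 or WT-1011 (medians -0.043, -0.049 and -0.059, adjusted p = 0.0612 to 0.108). The median of projection neuron markers was -0.088 and -0.077 without 1003 and 1017, that of cholesterol genes -0.13, -0.12 and -0.14 without 1003, 1023 and WT-1011, that of calcium genes -0.040 without 1023, and that of choroid plexus markers -0.45, -0.42, -0.47 and -0.38 without 1017, WT-1004, WT-1011 and WT-1018.

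At 12 months the genotypes differed in 187 genes. Ryr1 (probe set 10561561), the ryanodine receptor that releases calcium from internal stores, fell by 1.12 on the log2 scale, 2.17-fold, from 8.40 ± 0.08 in wild type (SD, n = 5) to 7.28 ± 0.15 in HdhQ150 (n = 6; limma adjusted p = 2.57e-11). Gpx6 fell by 1.49, 2.81-fold, from 8.21 ± 0.21 to 6.70 ± 0.15 (limma adjusted p = 1.24e-08). The early growth response factor Egr2 fell by 1.04 (SE 0.157, limma adjusted p = 0.000282), and Phex, already lower at 6 months, fell by 0.89 (SE 0.11, limma adjusted p = 2.5e-05). Further decreases included the phosphatase genes Dusp14 (-0.71) and Pdp1 (-0.59), the clock repressor Ciart (-0.69), the membrane transporter Slc4a11 (-0.66), the neuronal adhesion gene Cntnap3 (-0.61), Trank1 (-0.53) and the carbonic anhydrase relative Car11 (-0.45), with limma adjusted p from 1.86e-05 to 8.53e-05. The largest evidence for increases lay with Sfmbt2, a polycomb group gene (0.51 ± 0.0592 SE, limma adjusted p = 1.18e-05), Tmc3 (0.54), the RNA polymerase subunit gene Polr2a (0.48) and Kcng1 (0.53). Gng3 (0.41), Stmn2 (0.41), a neuronal microtubule regulator, the atypical cadherin Fat1 (0.43), Rgs19 (0.36), Lrrc41 (0.28) and Atp6ap1 (0.27) rose with limma adjusted p from 0.000228 to 0.00333. In all, 67 genes rose and 120 fell, and 157 of them differed by at least 1.2-fold. The count was 440 without wild-type mouse WT-454, and 115, 117, 124, 122 and 122 without 462, 464, WT-461, WT-508 and WT-527. It was 656 with array weights and 103 with only the groups compared.

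Striatal projection neuron markers shifted down at 12 months in the test with a preset correlation. Their median difference was -0.25 with 28 of 29 members negative (camera adjusted p = 4.98e-20, adjusted p = 0.0618 with an estimated correlation, fry adjusted p = 0.00983). 6 of the 29 fell over all genes, 15 were lower adjusted over the list alone, and 0 rose. Examples are the sodium channel subunit Scn4b, which fell by 0.82 (limma adjusted p = 0.000164), the cannabinoid receptor Cnr1, which fell by 0.61 (limma adjusted p = 0.000367), and the phosphodiesterase Pde10a, which fell by 0.49 (limma adjusted p = 0.000659). Indirect pathway markers had a median of -0.21 (camera adjusted p = 1.68e-06, adjusted p = 0.0618 with an estimated correlation, fry adjusted p = 0.00983). 3 of these 9 fell, the enkephalin gene Penk by 0.51 (limma adjusted p = 0.00118), Gpr6 by 0.50 (0.0254) and Gpr52 by 0.58 (0.0444), and 6 were lower adjusted over the list alone. Direct pathway markers did not shift (median -0.0036, mean 0.00083, camera adjusted p = 0.653), with Drd1 at -0.33, Tac1 at 0.33 and Pdyn at -0.14. Drd2 stood at -0.29 and Ppp1r1b at -0.27, and neither passed (limma adjusted p = 0.172 and 0.213). The difference between the direct and indirect pathway lists was not tested. Gpr6 did not pass without 462, 464, WT-461, WT-488 or WT-508 (adjusted p = 0.0588 to 0.0881, range without any mouse in turn 0.00798 to 0.0881), nor did Gpr52 without these or 451 or WT-527 (0.0696 to 0.153).

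Lists of signalling and activity genes also shifted down at 12 months with the preset correlation, and none of them held with an estimated correlation. Immediate early genes had a median of -0.27 (camera adjusted p = 7.73e-10, adjusted p = 0.155 with an estimated correlation, fry adjusted p = 0.0727). Egr2 and Homer1 (-0.54, limma adjusted p = 0.00707) fell, 14 of 16 did not pass, and 6 were lower adjusted over the list alone. Calcium signalling genes (median -0.12, camera adjusted p = 2.02e-10, adjusted p = 0.0625 with an estimated correlation) included Ryr1 and Camk4 (-0.38, limma adjusted p = 0.0253) as the 2 of 29 that fell, with 8 lower adjusted over the list alone. Circadian clock genes (-0.15, camera adjusted p = 1.8e-07, adjusted p = 0.0625 with an estimated correlation) included Ciart and Per1 (-0.41, limma adjusted p = 0.0243) as the 2 of 15 that fell, with 4 lower adjusted over the list alone. Of 37 potassium channel genes (median -0.11, camera adjusted p = 3.58e-09, adjusted p = 0.0955 with an estimated correlation), Kcnh4 fell by 0.43 (limma adjusted p = 0.000834), 36 did not pass, and 7 were lower adjusted over the list alone. Kcng1, which rose, is not on that list. Glutamate receptor genes (-0.056) and heat shock and chaperone genes (-0.073) had camera adjusted p = 0.00296 and 0.033 and adjusted p = 0.155 and 0.373 with an estimated correlation, with 0 members past by limma and 2 and 0 lower adjusted over the list alone. By fry the calcium, clock and potassium channel lists passed (adjusted p = 0.00983, 0.0155 and 0.0474). Camk4 did not pass without 462, 464, WT-488, WT-508 or WT-527 (adjusted p = 0.0537 to 0.0985), Per1 without 462, 487, 526, WT-461 or WT-527 (0.0607 to 0.0888), and heat shock genes without 453, 462, 487, 526, WT-461 or WT-508 (0.0558 to 0.22, median -0.033 without 462), while the glutamate receptor median was -0.11 without WT-454.

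Further lists shifted at 12 months with the preset correlation, and none of them held with an estimated correlation. Cortical excitatory neuron markers had a median of -0.10 (camera adjusted p = 0.0199, adjusted p = 0.571 with an estimated correlation), with 0 of 12 past by limma. The vesicular glutamate transporter Slc17a7 stood at -1.03 with an SE of 0.427 (limma adjusted p = 0.406). Per mouse, the mean of these markers was -0.77 ± 0.353 in HdhQ150 (SD, n = 6) and -0.46 ± 0.375 in wild type (n = 5). That list did not pass without 453, 462, 487, WT-454, WT-461 or WT-527 (adjusted p = 0.0591 to 0.223), and its median was -0.16, -0.19 and -0.20 without 464, WT-488 and WT-508. Clustered protocadherin genes, neuronal surface proteins encoded side by side, shifted up (median 0.23, 20 of 21 positive, camera adjusted p = 2.02e-10, adjusted p = 0.155 with an estimated correlation). Pcdhb15 rose by 0.25 (limma adjusted p = 0.0299), 20 of 21 did not pass, and 11 were higher adjusted over the list alone. Without wild-type mouse WT-454 the protocadherin median was 0.13 (adjusted p = 0.0348, range without any mouse in turn 1.62e-19 to 0.0348), and Pcdhb15 did not pass without 453, 464, 487, 526, WT-454, WT-461 or WT-508 (0.0516 to 0.091). Oligodendrocyte precursor markers (0.073, camera adjusted p = 0.033, adjusted p = 0.155 with an estimated correlation) had 1 of 8 higher, Olig1 at 0.37 (limma adjusted p = 0.0168), which was also the count adjusted over the list alone. Neither passed without 464, WT-454 or WT-527 (adjusted p = 0.0708 to 0.0805 for the list, whose median was 0.12 without WT-454, and 0.0519 to 0.0605 for Olig1). The list also failed without 487 and WT-461 (0.0678 and 0.0853), and Olig1 without 462 (0.0513). Proteasome subunit genes (0.068, 28 of 31 positive) and respiratory chain genes (0.058, 30 of 40 positive) shifted up with all arrays (camera adjusted p = 0.000504 and 0.00893, adjusted p = 0.373 and 0.382 with an estimated correlation), with 0 members past by limma and 2 and 1 higher adjusted over the list alone. Without mouse WT-454 the proteasome median was -0.00082 and the respiratory median 0.027 (camera adjusted p = 0.748 and 0.925), and both tests pointed down. Respiratory chain genes also failed without 487 and WT-527 (0.0536 and 0.0708) and had a median of 0.09 without WT-461. Among glia, S100b rose by 0.38 (limma adjusted p = 0.0051), the other 14 of 15 astrocyte markers did not pass (list median -0.011, mean 0.014, camera adjusted p = 0.992), and Gfap stood at 0.14.

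At 18 months 27 genes differed. Scn4b fell by 0.91 on the log2 scale (SE 0.138), Penk by 0.73, from 12.25 ± 0.14 to 11.52 ± 0.25 (SD, n = 4 each), Ryr1 by 0.63 and Pde10a by 0.61, with limma adjusted p from 0.00025 to 0.000814. Gpx6 again showed the largest decrease, 1.17 or 2.25-fold, from 7.38 ± 0.19 to 6.21 ± 0.22 (limma adjusted p = 0.000144). Slc4a11 (-0.61), Traip (-0.42), a ubiquitin ligase gene, and Car11 (-0.37) fell with limma adjusted p from 0.00372 to 0.0044, and Gpr6 (-0.71) and the carbonic anhydrase Car12 (-0.62) with 0.0118 and 0.0196. Among the increases, Enpp6, an oligodendrocyte phosphodiesterase, rose by 0.76, 1.7-fold, from 6.98 ± 0.22 to 7.74 ± 0.08 (limma adjusted p = 0.000751). Cd82 (0.50), the kinase genes Prkcq (0.52) and Hipk2 (0.33), Tmc3 (0.54), the semaphorin receptor Plxnb3 (0.50) and S100b (0.47) rose with limma adjusted p from 0.000804 to 0.00916. Sema3d (0.54), Pdk4 (0.37) and Tns3 (0.31) rose with limma adjusted p = 0.0209, 0.0265 and 0.0377. Drd1 at -0.46, Drd2 at -0.44, Adcy5 at -0.46 and Cnr1 at -0.30 did not pass (limma adjusted p = 0.115, 0.13, 0.0559 and 0.564), nor did Ppp1r1b at -0.30, Pdyn at -0.18, Tac1 at -0.01 and Gfap at 0.03 (0.499 to 1). In all, 11 genes rose and 16 fell. The count was 15 without mouse WT-400, 16 without 426, 41 without 415 and 41 without the 12-month mouse WT-454, and it was 1, Gpx6, when the 8 arrays of this age were fitted alone. Calls of Car12, Gpr6, Sema3d, Pdk4, Tns3 and S100b were lost without single mice. Mice 412 and WT-400 ended those of Gpr6 (adjusted p = 0.0772 and 0.105), Car12 (0.12 and 0.105), Sema3d (0.131 and 0.0888) and Pdk4 (0.0621 and 0.131). Mouse 426 ended those of all 6 genes (0.0687 to 0.161), 383 those of S100b, Car12, Pdk4 and Tns3 (0.0653 to 0.17), WT-414 those of Car12 and Tns3 (0.0945 and 0.0794), WT-431 and WT-401 those of Sema3d, Pdk4 and Tns3 (0.0591 to 0.111), and WT-400 and 415 that of Tns3 (0.175 and 0.103).

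Among the lists at 18 months, projection neuron markers lay lowest, with a median of -0.26 and 28 of 29 members negative (camera adjusted p = 1.97e-25, adjusted p = 0.0233 with an estimated correlation). Pde10a, Scn4b and Rasgrp2 (-0.52, limma adjusted p = 0.0466) were the 3 that fell, and 17 were lower adjusted over the list alone. Indirect pathway markers had a median of -0.23 (camera adjusted p = 4.41e-10, adjusted p = 0.00785 with an estimated correlation), with Penk and Gpr6 as the 2 of 9 that fell and 5 lower adjusted over the list alone. These 2 lists were the ones that held with an estimated correlation, and fry called them too (adjusted p = 0.0129 and 0.00155). Direct pathway markers had a median of -0.029 (camera adjusted p = 0.0616). Clustered protocadherin genes shifted up (median 0.23, 21 of 21 positive, camera adjusted p = 9.83e-14, adjusted p = 0.0871 with an estimated correlation). None of them passed by limma and 2 were higher adjusted over the list alone, with Pcdhb21 at 0.48 and Pcdhb22 at 0.39. Oligodendrocyte markers shifted up (0.17, camera adjusted p = 3.6e-05, adjusted p = 0.213 with an estimated correlation) with 0 of 14 past and 3 higher adjusted over the list alone, among them Mog at 0.33 and Cnp at 0.33. Precursor markers did likewise (0.079, camera adjusted p = 0.00392, adjusted p = 0.0836 with an estimated correlation), with 0 of 8 past and 2 higher adjusted over the list alone. Glucocorticoid response genes shifted up (0.10, camera adjusted p = 0.000954, adjusted p = 0.0585 with an estimated correlation, fry adjusted p = 0.0417), where Pdk4 was the 1 of 12 that rose over all genes and over the list alone. Rasgrp2 did not pass with mouse 1023 entered as male (-0.52, adjusted p = 0.0603), with no sex term, in females alone, with no trend or with median centring, nor without 383, 412, 426, WT-400, WT-401 or WT-414 (adjusted p = 0.0679 to 0.385), Gpr6 without 412, 426 or WT-400 (0.0772 to 0.105) and Pdk4 without 383, 412, 426, WT-400, WT-401 or WT-431 (0.0621 to 0.161). The glucocorticoid median was 0.054, 0.061 and 0.064 without 426, WT-414 and WT-431 and 0.15 without WT-401.

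Other lists shifted at 18 months as well. Calcium signalling genes (median -0.11, 1 of 29 lower, 2 adjusted over the list alone), potassium channel genes (-0.097, 0 of 37 and 2), glutamate receptor genes (-0.070, 0 of 22 and 4) and GABA receptor genes (-0.088, 1 of 13 and 2) shifted down, with camera adjusted p = 4.36e-07, 3.6e-05, 0.00186 and 0.00186. Their adjusted p with an estimated correlation was 0.113, 0.213, 0.152 and 0.0836. The GABA receptor subunit Gabra2 fell by 0.81 (limma adjusted p = 0.0466). Proteasome genes (0.075, 29 of 31 positive), respiratory chain genes (0.050, 30 of 40 positive) and endothelial and mural cell markers (0.086, 9 of 13 positive) shifted up with 0 members past by limma or adjusted over the list alone. Their camera adjusted p was 0.000983, 0.00353 and 0.0156, and their adjusted p with an estimated correlation 0.359, 0.359 and 0.213. Leaving out mouse 383 ended the calls of the glutamate receptor (median 0.00037, adjusted p = 0.25), GABA receptor (-0.052, 0.0703) and endothelial lists (0.076, 0.129), and moved the potassium channel median to -0.045. Mouse WT-400 also ended the endothelial call (0.0828), and the endothelial median was 0.14 without 415 and 0.043 without 426. The glutamate receptor median was -0.13 without 426, the GABA receptor median -0.051 without WT-401, the potassium channel median -0.064 and -0.15 without WT-401 and WT-431, and the respiratory median 0.026 without WT-431. Gabra2 did not pass with mouse 1023 entered as male (-0.81, adjusted p = 0.0515), array weights, robust eBayes, no trend or median centring, nor without 383, 412, 415, WT-400, WT-401, WT-414 or WT-431 (adjusted p = 0.091 to 0.266). Lists that shifted at no age were, with camera adjusted p at 12 months, striatal interneuron (0.0508, past the threshold with mouse 1023 entered as male), direct pathway (0.653), thalamic (0.733), ependymal (0.521) and astrocyte markers (0.992), interferon response (0.886), complement and antigen presentation (0.813) and homeobox cluster genes (0.813). Choroid plexus markers at 18 months had a median of 0.0091 while the camera test pointed down (camera adjusted p = 0.849), and presynaptic genes at 12 months had a median of -0.037 while it pointed up (0.813). The blood marker list had 1 measured gene, Alas2, which stood at -0.09 at 12 months (limma adjusted p = 0.82).

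**Figure D2:**
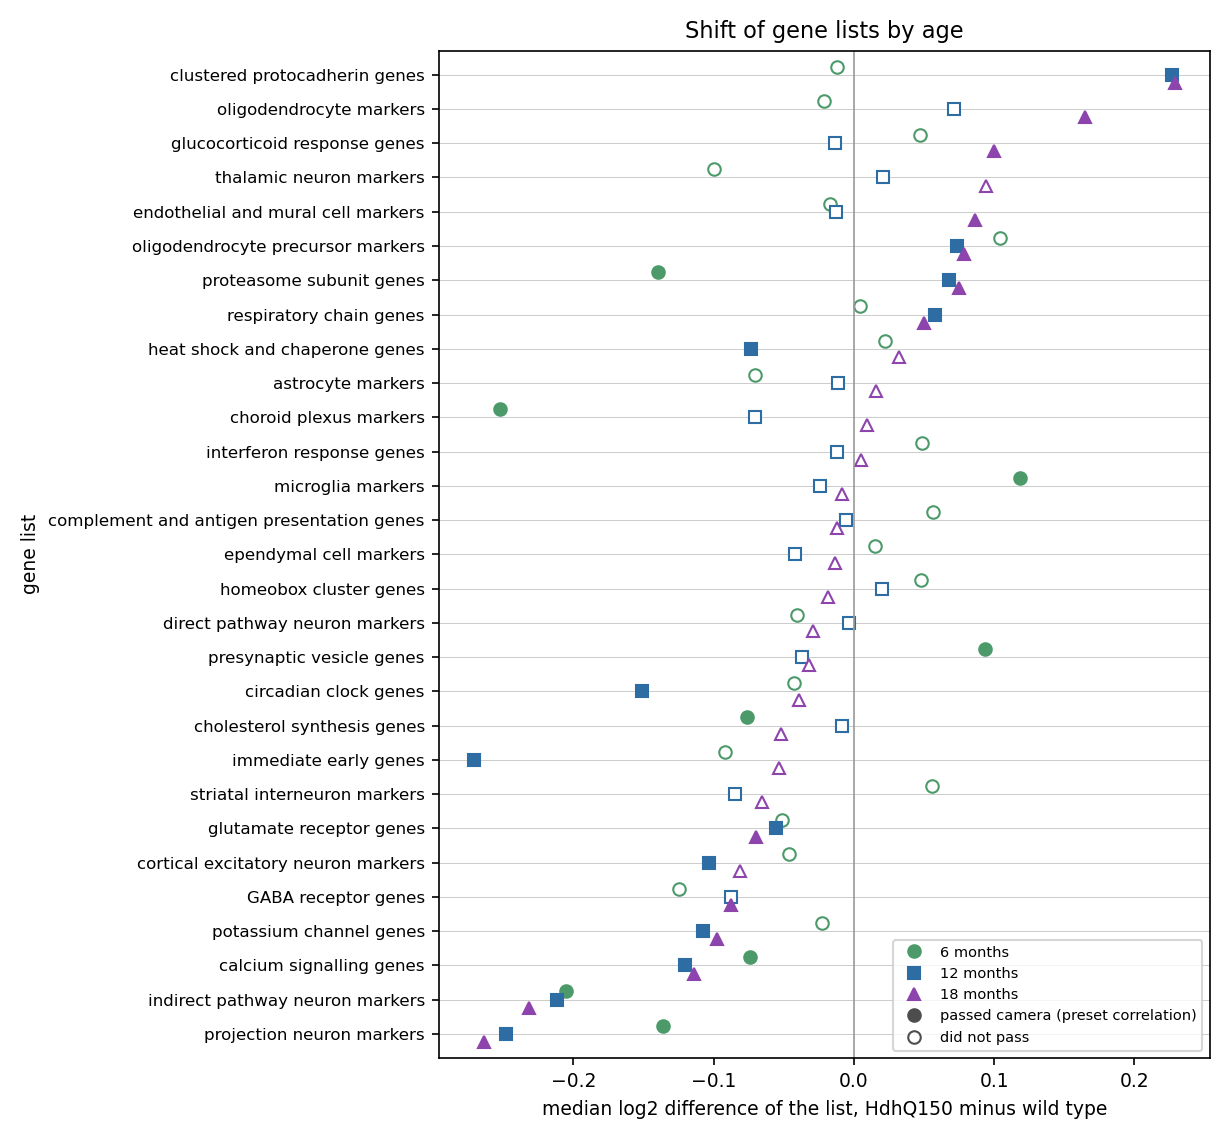
Median log2 difference (HdhQ150 minus wild type) of each gene list at 6, 12 and 18 months, filled where the camera test with a preset correlation passed and open where it did not. Projection neuron markers lie at -0.14, -0.25 and -0.26 at the successive ages, and clustered protocadherin genes at -0.012, 0.23 and 0.23.

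The genotype differences were next compared between ages. Ryr1 was the 1 gene whose difference changed between 6 and 12 months, from -0.34 to -1.12, a change of -0.78 (SE 0.105, limma adjusted p = 0.00068). Between 12 and 18 months 0 genes passed by limma, with 412 at an unadjusted p under 0.05, and between 6 and 18 months 0 passed, with 1629 at an unadjusted p under 0.05 and a smallest adjusted p of 0.471. When nothing differs, a share of 0.05 of the 19938 genes is expected there, more than 412 and fewer than 1629. Genes are not independent, so neither count measures a change. Array weights gave 0 and 6, and robust eBayes, no trend and no sex term gave 0 for both. All 5 genes called at 6 months were also called in the same direction at 12 months, where independent lists would share 0.00336 higher and 0.0241 lower genes. Of 27 genes called at 18 months, 23 were shared with 12 months (8 higher and 15 lower, against 0.037 and 0.0963 for independent lists), and Gpx6 was shared between 6 and 18 months. The ages share 1 estimate of the spread and 1 sex term for each gene. Their calls are thus not independent, and the numbers for independent lists are no exact chance level. Across genes, which are not independent replicates, the log2 differences correlated with r = 0.266 between 6 and 12 months, 0.384 between 12 and 18 and 0.0183 between 6 and 18. Of the 187 genes called at 12 months, 181 had the same sign at 18 months, and 0 of 69 regroupings of the 18-month mice reached that number (highest 172). At 6 months 170 of the 187 had the same sign, with 3 of 99 regroupings as high. Of the 27 genes called at 18 months, 26 had the same sign at 12 months, with 21 of 99 regroupings as high, and 26 at 6 months, with 0 of 99. The 5 genes called at 6 months kept their sign at 12 and 18 months, with 37 of 99 and 8 of 69 regroupings as high, so this count alone did not exclude chance for them. Of these, Kcng1 stood at 0.02 at 18 months (SE 0.0816, limma adjusted p = 0.998), so its sign there carries no difference. The glucocorticoid response list changed between 12 and 18 months (median change 0.13, camera adjusted p = 0.00012, adjusted p = 0.0384 with an estimated correlation, fry adjusted p = 0.191). Between 6 and 12 months the protocadherin list changed by 0.26 and the proteasome list by 0.13 (camera adjusted p = 1.68e-06 for both), and neither held with an estimated correlation (adjusted p = 0.558 for both). Without mouse WT-454 their 12-month medians went from 0.23 to 0.13 and from 0.068 to -0.00082, and the changes of lists between ages were not refitted without single mice. These tests on lists between ages were chosen after the data were seen.

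Wild-type mice also differed between ages. At 12 against 6 months, the neuronal genes Vsnl1, a calcium sensor, and Stmn2 fell by 1.16 and 0.98, 2.24-fold and 1.97-fold, from 12.62 ± 0.14 to 11.47 ± 0.16 and from 10.93 ± 0.10 to 9.96 ± 0.21 (SD, n = 5 each; limma adjusted p = 2.36e-09 for both). Ywhah (-0.81), Spaca6 (-0.72) and G6pc3 (-0.59) fell as well. The glutamate receptor auxiliary subunit gene Cacng4 rose by 0.68, Jcad by 0.66, Carhsp1 by 0.64, the striatum-enriched phosphatase Ptpn5 by 0.54 and Sh2d5 by 0.50, with limma adjusted p from 1.57e-06 to 8.73e-06. Projection neuron markers shifted up (median 0.37, 18 of 29 higher, 0 lower, 22 higher and 2 lower adjusted over the list alone, camera adjusted p = 9.27e-08, adjusted p = 0.321 with an estimated correlation). Cortical excitatory neuron markers shifted down (-0.66, 9 of 12 lower, 11 adjusted over the list alone, camera adjusted p = 9.34e-06), and so did presynaptic vesicle genes (-0.27, 13 of 21 lower and 1 higher, 15 and 1 adjusted over the list alone) and cholesterol synthesis genes (-0.23, 10 of 19 lower, 11 adjusted over the list alone), with camera adjusted p = 9.34e-06 and 1.81e-05. None of these 4 held with an estimated correlation (adjusted p = 0.321 each), and fry called all 4 (adjusted p = 0.000747 to 0.00322). In all, 5121 genes changed, 2612 higher and 2509 lower, which median centring of the arrays turned to 1884 higher and 3347 lower. Without wild-type mouse WT-454 the count was 3302.

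From 12 to 18 months Stmn2 rose by 0.96 and Vsnl1 by 0.89. Both had fallen from 6 to 12 months, but the comparisons share the 12-month arrays with opposite sign and a return was not tested. Also higher were Syt17 (1.30), Sphkap (1.22) and Dipk2a (0.65), and limma adjusted p of the 5 genes ran from 2.57e-08 to 1.44e-05. Egr2 fell by 1.54, 2.91-fold, the retinoid receptor genes Rxrg and Rarb by 1.03 and 0.83, the serotonin receptor gene Htr1b by 0.97 and Zswim6 by 0.61, with limma adjusted p from 3.36e-06 to 1.67e-05. Projection neuron markers shifted down (median -0.53, 22 of 29 lower, 23 lower and 1 higher adjusted over the list alone, camera adjusted p = 1.39e-32, adjusted p = 0.0146 with an estimated correlation). Cortical markers shifted up (0.76, 7 of 12 higher, 11 adjusted over the list alone, camera adjusted p = 1.97e-11, adjusted p = 0.0576 with an estimated correlation). Immediate early genes shifted down (-0.57, 12 of 16 lower, 13 adjusted over the list alone, camera adjusted p = 7.89e-16, adjusted p = 0.0568 with an estimated correlation), and cholesterol synthesis genes up (0.19, 6 of 19 higher, 12 adjusted over the list alone, camera adjusted p = 5.85e-11, adjusted p = 0.0429 with an estimated correlation). The mean of the cortical markers was 0.37 ± 0.27 (SD) in wild type at 6 months (n = 5), -0.46 ± 0.375 at 12 (n = 5) and 0.51 ± 0.304 at 18 (n = 4), and in HdhQ150 0.31 ± 0.305 (n = 5), -0.77 ± 0.353 (n = 6) and 0.38 ± 0.34 (n = 4). In all, 1171 genes changed, 759 higher and 412 lower, and 696 changed without mouse WT-401. The count was 2027 with array weights and 197 with the cortical marker mean as a covariate, which overlaps with age.

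**Figure D3:**
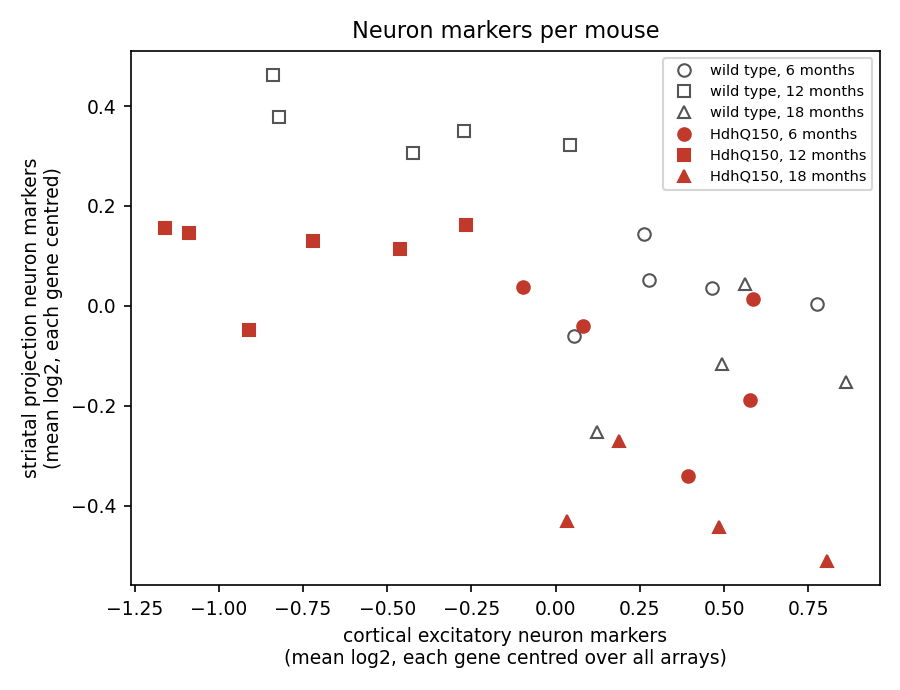
Mean log2 level of striatal projection neuron markers against that of cortical excitatory neuron markers in each mouse, each gene centred over all 29 arrays, wild type open and HdhQ150 filled, with a symbol for each age. The group means at 12 months lie lowest on the cortical axis, with HdhQ150 mice at -1.16 to -0.267 against -0.0966 or more at the other ages, and wild-type mice at -0.839 to 0.0433 against 0.0545 or more.

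Between 6 and 18 months the complement gene C4b rose by 1.18 in wild type, 2.27-fold, from 7.61 ± 0.06 (SD, n = 5) to 8.80 ± 0.30 (n = 4; limma adjusted p = 1.19e-07). The secretory granule gene Chga (0.71), the metabolic enzyme gene Tkt (0.48), Tmem141 (0.46) and Dexi (0.39) rose with limma adjusted p from 0.000217 to 0.000404. The peptide processing gene Pcsk1n fell by 0.90, the metallothionein gene Mt2 by 0.85, the trafficking GTPase gene Arf1 by 0.63, Rnasek by 0.62 and Etv3 by 0.58, with limma adjusted p from 7.52e-08 to 4.53e-05. Immediate early genes shifted down (median -0.40, 3 of 16 lower, 8 adjusted over the list alone, camera adjusted p = 5.15e-07), as did circadian clock genes (-0.17, 2 of 15 lower, 4 adjusted over the list alone, camera adjusted p = 0.000399), and neither held with an estimated correlation (adjusted p = 0.476 for both). Glucocorticoid response genes had a median of 0.033 and a mean of -0.12, and the test pointed down (camera adjusted p = 0.0317, adjusted p = 0.476 with an estimated correlation), with 4 of 12 lower and 1 higher and 5 lower adjusted over the list alone. In all, 1250 genes changed, 662 higher and 588 lower, which median centring turned to 513 higher and 727 lower. The count was 2437 without wild-type mouse WT-1011, and 490, 709, 729, 780 and 590 without WT-400, WT-414, WT-431, WT-1018 and WT-1020. The labels give no array batch, so age and any batch shared by mice of 1 age cannot be told apart.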

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

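The tests on mouse WT-454 and on mouse 1023, and the fits without them, were chosen only after the results were seen. In 227 groups of values, 22 held a mouse far from the others of its group, and chance gives about 1 in 20 groups, or 11. The groups of values reuse the same mice and are not independent, and mice WT-454 and 1023 recur among the 22. The excess over 11 is thus no measure of how many mice stood apart.

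HdhQ150 mouse 1023 at 6 months, labelled female, stood far from the other labelled females in Xist (5.95) and from the other HdhQ150 mice in Htt (8.88) and Ryr1 (7.71). An exchange with a wild-type mouse was tested with a score over the 187 genes changed at 12 months. Mouse 1023 scored 0.514, above every wild-type mouse of that age (-0.176 to 0.288) and below every other HdhQ150 mouse (0.732 to 1.15). An exchange predicted a score within the wild-type range, which it missed, but it missed the HdhQ150 range too, so the score cannot decide. Mouse 1023 also had Htt below that of every wild-type mouse of that age (9.11 or more). The score lay 0.226 above the highest wild-type mouse, as predicted for a wrong sex label or an exchange with another HdhQ150 mouse. That prediction did not ask for a score among the other HdhQ150 mice, so it cannot decide either. An exchange of a female with a labelled male of this series would leave female expression under a male label. The 6 labelled males had Xist at 5.50 to 6.13, against 11.11 or more in the other labelled females. This argues against such an exchange, with a wild-type or an HdhQ150 mouse. A wrong sex label and an exchange with a mouse outside the series stay open. The 6-month count of 5 was 3 with the mouse entered as male and 188 without it, so the sex label does not account for the 188.

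Wild-type mouse WT-454 at 12 months, the lone male of its group, had a mean correlation of 0.945 with the other arrays of its group. It also lay far from them in the means of ependymal markers (0.38), homeobox cluster genes (0.448), proteasome genes (-0.349), protocadherin genes (-0.563), glutamate receptor genes (-0.156), GABA receptor genes (-0.297) and calcium signalling genes (-0.0798). Without it the 12-month genotype count was 440 against 187, and the 12 against 6 months wild-type count kept 64.5% of its size, which argues against this array as the whole cause of the age difference. The 5 other labelled males had correlations of 0.980 to 0.986 within their groups, against 0.945 for this mouse. Most of the mice they were set against were females, which argues against its sex alone, though each group also held another mouse with male expression. Array weights were 0.862 to 1.88 for these males and 0.106 for this mouse. The fit behind the weights holds a sex term, so they say nothing about sex. A fault of the array and the biology of this mouse stay open, and no biological explanation was tested.

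Other single mice stood apart with no test of a cause. HdhQ150 mouse 462 at 12 months had the mean of projection neuron markers at -0.0485 and of thalamic markers at -0.00729, and HdhQ150 mouse 453 had glutamate receptor genes at -0.223. Wild-type mouse WT-461 at 12 months had Gpx6 at 8.58. At 18 months, HdhQ150 mouse 415 had astrocyte markers at -0.0392, HdhQ150 mouse 383 had microglia markers at 0.245 and complement and antigen presentation genes at 0.545, and wild-type mouse WT-431 had thalamic markers at 0.488. At 6 months, HdhQ150 mouse 1017 had choroid plexus markers at 1.1, HdhQ150 mouse 1016 had heat shock genes at 0.146, and wild-type mouse WT-1011 had respiratory chain genes at -0.0631.

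Differences between ages passed for 1 gene and, with an estimated correlation, for 1 list, while others, such as protocadherin and proteasome genes between 6 and 12 months, passed with the preset correlation alone (camera adjusted p = 1.68e-06 for both, adjusted p = 0.558 with an estimated correlation). Without mouse WT-454 the 12-month medians of these 2 lists went from 0.227 to 0.129 and from 0.0678 to -0.00082. The genotype difference of Ryr1 changed by -0.78 between 6 and 12 months (limma adjusted p = 0.00068). The median of glucocorticoid response genes changed by 0.131 between 12 and 18 months, with 11 of 12 members in that direction (adjusted p = 0.0384 with an estimated correlation, fry adjusted p = 0.191).

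Probe sets outside the gene comparisons also passed, in a fit of all 35556 probe sets with p adjusted over all of them. Of 12146 with no gene name here, 14 differed between genotypes at 12 months (6 higher, 8 lower) and 2 at 18 months, both higher, and of 1621 with several gene names 3 differed at 12 months, all higher.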

How the results depend on the processing

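The fits without mouse WT-454 or 1023 where not compared, without both, with 1023 as male, with the cortical marker mean as a covariate, and camera on differences between ages were chosen only after the data were seen. No paired analysis was possible because the groups share no animal numbers. Over 41 called genes followed at 12 months, some of them not named in the text, 897 of 979 values kept their call and 82 lost it, 404 of 480 at 18 months and 89 of 113 at 6 months kept it, and the 30 genes named for wild-type ages kept theirs under every alternative, as Ryr1 did between 6 and 12 months (33 of 33). The 6-month count (5) was 3 with all probe sets, no sex term, the brighter genes, median centring or 1023 as male, 2 in females, 11 with only the groups compared, 12 with the covariate, 868 without both mice and 1330 with array weights, which called all 5 again. Lists shifted at 6 months (8) fell to 0 with an estimated correlation and by fry, 5 with only the groups compared and 2 with the brighter genes. Htt at 6 months lost its call in labelled females (-0.36, limma adjusted p = 0.125) and ran from -0.415 to -0.364 over its alternatives. The labelled females include mouse 1023, and no fit of females without it was made. Calls lost in females at 6 months are thus not a result of females alone. With 1023 as male Phex and Insig1 at 6 months and Rasgrp2 and Gabra2 at 18 months lost theirs. At 12 months (187) the count was 103 with only the groups compared, 281 after a second quantile normalization, about 5.1e+02 without both mice and 656 with array weights, which shared 175 of the 187. Lists there (13) were 0 with an estimated correlation and 5 by fry. Proteasome and respiratory chain genes turned without WT-454 (-0.00082 and 0.0271) and without both mice (-0.00536 and 0.0276), as cortical markers did with their own mean as covariate (0.0823), which its construction explains. At 18 months (27) the count was 1 with only the groups compared and 43 without both mice, and lists (13) were 2 with an estimated correlation and 3 by fry. Between 6 and 12 months 2 genes passed without both mice (1), and between 6 and 18 months 6 with array weights (0 by limma, 1629 at an unadjusted p under 0.05). In wild type, 12 against 6 months (5121) gave 2434 in females, 2888 with the brighter genes (579 higher, 2309 lower), 3408 without both mice and 1752 with the covariate; 18 against 12 (1171) gave 2027 with weights and 197 with the covariate; 18 against 6 (1250) gave 2375 with all probe sets, 708 in females, 248 with only the groups compared, 694 with the brighter genes and 2395 with weights. Leaving out each mouse in turn gave 3 to 188 genes and 5 to 13 lists at 6 months, 115 to 440 and 10 to 15 at 12, and 15 to 41 and 11 to 19 at 18. For the changes between 6 and 12, 12 and 18 and 6 and 18 months it gave 1 to 2, 0 to 0 and 0 to 0 genes. In wild type it gave 3302 to 6521, 696 to 1437 and 490 to 2437. The 12-month median of proteasome genes ran from -0.00082 to 0.0941 and that of respiratory chain genes from 0.0271 to 0.090. Fewer arrays or genes tested lower some counts by construction, and for the rest the cause was not tested.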

Other observations

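The tests on wild-type mouse WT-454, on mouse 1023, the covariate fit and the direction counts across ages were chosen only after the results were seen. HdhQ150 mice changed with age as well. From 6 to 12 months 4599 genes changed in HdhQ150 (2372 higher, 2227 lower), from 12 to 18 months 1154 (833 higher, 321 lower) and from 6 to 18 months 927 (473 of them lower). The 12 minus 6 months differences of the 2 genotypes, which share no arrays, correlated across genes with r = 0.807 (0.817 without mouse WT-454).

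The wild-type difference between 6 and 12 months went with low group means of the cortical markers at 12 months in both genotypes. A different share of cortical tissue in the dissections may contribute. The slope of each gene on the cortical markers within groups was correlated across genes with the wild-type difference between these ages. That difference was taken as 6 minus 12 months, the direction in which the markers are higher (r = 0.287, 0.358 without mouse WT-454). With the marker mean as a covariate the count went from 5121 to 1752, but the covariate overlaps with age, which lowers precision, and Vsnl1 and Stmn2 kept their calls at -0.93 and -0.81, so the lower count alone is no evidence for this share. This share, age itself and a batch shared by all mice of 1 age (r = 0.807 between genotypes) cannot be told apart, because the labels give neither the dissections nor the batches.

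Strain variants around the knock-in allele may alter genes beside Htt. Of 41 such genes 0 passed at any age (limma), and 7, 8 and 1 had an unadjusted p under 0.05 at 6, 12 and 18 months. At 12 months that was 19.5% against 8.95% of other genes (Fisher p = 0.0272), and at 6 and 18 months 17.1% against 13.7% (p = 0.496) and 2.44% against 5.82% (p = 0.732). The upper bound of the odds ratio of passing at 6 months was 738, so an excess and none cannot be told apart with so few calls.

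Enpp6, higher in HdhQ150 at 12 and at 18 months, is expressed by oligodendrocytes, and more newly formed oligodendrocytes could raise it. A list of 17 genes of that stage, without the genes already called, had a median of 0.0791 at 18 months with 12 of 17 positive (camera adjusted p = 0.002, adjusted p = 0.0721 with an estimated correlation, fry adjusted p = 0.0527). At 12 months, where Enpp6 was already called, the median was 0.032 and the list did not pass (camera adjusted p = 0.472). None of the 17 passed at 18 months by limma, which leaving out the called genes fixed in advance, so this says nothing about a shift. Adjusted over the list alone 3 passed. The tests of the list differed, so more such cells, higher expression per cell and no shift of the list at all cannot be told apart.

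Other splits of the same mice were fitted for each count between genotypes or ages, and the numbers of splits below include the real one. At 12 months 2 of 100 splits gave as many as 187 (highest other 251, with 453 and WT-454 exchanged), and at 18 months 1 of 35 did (27 against 0). For wild type by age, 1 of 100 did so at 12 against 6 months (5121 against 5007 with WT-1011 and WT-461 exchanged). The same held for 1 of 100 at 18 against 12 (1171 against 1139) and 3 of 100 at 18 against 6 (1250 against 2474). The last 2 highest splits were near mirrors of the real one, with all mice but WT-454 or all but WT-1011 exchanged. Chance is less likely for these counts but not excluded, since at most 100 splits were fitted and the shares were not adjusted over the counts. It was not excluded at 6 months either, where 6 of 100 splits gave as many as 5 and exchanging 1003 and WT-1011 gave 469. For the changes between ages, residuals were shuffled among the mice of each genotype instead. Chance was not excluded for the change between 6 and 12 months (6 of 100, the real one included, 1 against 768). Between 12 and 18 months (100 of 100, 0 against 2630) and between 6 and 18 months (100 of 100, 0 against 40) the real count was 0. Every shuffle reaches that, so these shuffles say nothing about chance. By limma 412 and 1629 genes had an unadjusted p under 0.05 for these last 2, and array weights gave 0 and 6. When nothing differs, a share of 0.05 of the 19938 genes is expected there. That is more than the 412, so the 412 are no sign of a change. What drives the splits or shuffles with several times the real count, such as 469 and 768, was not tested.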
